A study of Solanum lycopersicum with 3 samples.

How the data were processed

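RNA from tomato (Solanum lycopersicum, cultivar Ailsa Craig) fruit pericarp was measured on the Affymetrix tomato GeneChip, with 3 arrays in 3 groups of 1 array each. Per the labels' protocols, 10 to 12 g of tissue was used for each preparation. The Ex1 preparation used 1 ml of a phenol-containing buffer per g and was mixed at once with phenol and chloroform. The Ex2 preparation used 2 ml per g of a high-salt Tris buffer with sucrose and magnesium. Cell debris was then spun out at 10000 x g for 15 min, and RNA was taken from the supernatant after detergent and phenol were added. The third preparation is RNA from the cell debris pellet, extracted by the Ex2 method. Its extraction text is the same as that of the Ex2 preparation, so how the pellet was taken up is not given in the sources used here.

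The deposited values are probe set intensity values on a linear scale, as their range shows. The submitters' processing notes name GCOS 5.0 and RMA, with no version for RMA and no order or parameters for either. The table holds 10209 probe sets and 3 columns, and no column of another sample. Of the probe sets, 171 are controls, 63 of them for reporter genes. The other 10038 had median intensities of 179 (Ex1), 177 (Ex2) and 170.0 (pellet), so the arrays had near-equal distributions when deposited. Of these, 946 had the same value on all 3 arrays and a further 1524 on exactly 2. A log2 difference of 0 can therefore be an exact tie in the deposited table.

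Gene names came from the platform annotation, which is old, and were updated through the Entrez gene ID with the RefSeq gene table of assembly SLM_r2.1. Exactly 1 name was given for 909 probe sets, several for 0 and none for 9129. The named probe sets stand for 803 genes, and 885 of the probe sets had a gene ID in the RefSeq table. An unnamed probe set is unnamed here, not without a gene. The annotation used here gives symbols without descriptions, so genes entered lists by current, older or platform symbol. Where a gene had several probe sets, the one with the highest mean over the 3 arrays was used. Coordinates and sequences were not used here, so the planned comparison of genes with and without a predicted signal sequence or membrane span was not run.

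All comparisons were made on log2(intensity + 1). Fold changes are on that scale and so understate differences of dim genes. With 1 array per group there is no replicate check and no test: no p-value or standard error was computed. A probe set or gene entered a comparison if the brighter of its values on the compared arrays reached the median of all non-control values, an intensity of 175 (7.46 on the log2 scale). Probe sets and genes at least 2-fold apart were counted, a log2 difference of 1. For each gene list the median difference over members passing the filter was set against the medians of 10000 random lists. These had the same size, were matched in 10 bins of mean expression, and were drawn from all non-control probe sets that passed the filter. The percentile describes these arrays only and is given for lists with at least 3 members. A list outside the central 95% of random lists is described as outside their range.

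The gene lists (16 by function and route of the protein, 4 by cell type), the contrasts and the alternatives were set before the data were examined. A further 12 lists and 3 alternatives were added afterwards, as stated where they are used. The named genes are, for each contrast, the 12 highest and the 12 lowest log2 differences among genes with 1 name that pass the filter. Within each list they are the members furthest from 0 and the brightest member. Control probe sets were read as checks of the arrays and the RNA.

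The alternatives were no filter, a filter at the upper quartile, arrays centred on their medians, quantile normalization, and scaling on cytosolic ribosomal proteins. Others were the mean of a gene's probe sets, leaving out probe sets with the suffixes for cross-hybridising designs, a pseudocount of 16, thresholds of 3-fold and 1.5-fold, and unmatched random lists. Scaling on hybridisation spikes, random lists from named genes, and leaving out TPx1 and ER24, whose list membership rests on ambiguous symbols, were added afterwards. Under the scaling alternatives the choice of bright genes was kept. The code was tested on simulated data for Ex2 minus Ex1 over 10209 probe sets with noise of 0.2 (SD, log2). All 200 probe sets given 4-fold differences passed 2-fold, against 3 of 9838 others, and 5 of 100 random lists of 15 genes fell outside the 95% range. The simulated noise was independent between probe sets, so these counts check the code and give no error rate for the real arrays. Work was done in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.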

Results

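The series compared transcripts recovered from tomato fruit pericarp by different RNA extraction protocols. The question, from the study's title and design, was whether a method based on a high-salt buffer recovers mRNAs of secreted and endomembrane proteins. There were 3 arrays, 1 each for the Ex1 extract, the Ex2 supernatant extract and the Ex2 cell debris pellet. No group had a replicate, so each difference below is between single arrays and its spread between samples is unknown. Their number limits the precision. Across the 10038 non-control probe sets, which are not independent replicates, Ex1 and the pellet had a Pearson correlation of 0.98 on the log2 scale. The correlation of Ex2 was 0.94 with each of the other arrays. Among genes with several bright probe sets, their log2 differences lay a median of 0.22 apart for Ex2 minus Ex1 (26 genes), 0.38 for pellet minus Ex2 (24 genes) and 0.18 for pellet minus Ex1 (25 genes). That gap is measured within arrays, not between samples.

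The arrays also differed in control signals. The hybridisation spikes bioB, bioC and bioD, bacterial RNAs added at hybridisation, were 2.33-fold brighter at the median of 21 probe sets on Ex2 than on Ex1. They were 1.50-fold brighter on the pellet than on Ex1. The 25S ribosomal RNA probe set read 1809 on Ex1, 367 on Ex2 and 568 on the pellet, and the 17S probe set read 55.3, 23.2 and 23.9. Scaling the arrays on the spikes shifted the median of all non-control probe sets by -1.19 for Ex2 minus Ex1, 0.55 for pellet minus Ex2 and -0.64 for pellet minus Ex1. Scaling on the ribosomal protein genes RPL3 and RPL8 shifted it by 0.55, -0.44 and 0.11. Directions below are on the deposited scale. The difference of a single gene turns direction with a scaling whose opposite shift is larger, and list medians that turned are named as such.

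The first comparison, Ex2 minus Ex1, set the supernatant method against the direct phenol method. Transcripts of cell wall enzymes, secreted defence proteins, membrane transporters and ethylene receptors were higher in Ex2, many of them 3-fold to 12-fold. Among named genes the largest difference was in GP1, the noncatalytic polygalacturonase beta subunit, at 12.3-fold. It was followed by the beta-galactosidase gene TBG2 at 11-fold, the endoglucanase gene Cel1 at 10.4-fold, TBG5 at 9.94-fold and the pectin methylesterase gene PMEU1 at 9.68-fold. The metallothionein genes MT2 and MTA, the copper chaperone gene CCH and the photosystem gene psaD were lower in Ex2, by less than 3-fold.

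Of 495 named genes that passed the brightness filter, 100 were at least 2-fold higher in Ex2 and 23 at least 2-fold lower. Over all 5568 probe sets that passed it, 964 were at least 2-fold higher and 560 lower, with a median difference of -0.25. With scaling on ribosomal proteins the named genes split 136 higher to 0 lower, and on the spikes 50 to 320. The probe sets split 1252 to 28 and 438 to 3993. The split between higher and lower therefore rests on the scaling, while the place of a list relative to random lists does not move with a constant shift.

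Cell wall enzymes and wall proteins had the most bright members of the lists set beforehand, with 23 of the list's 42 genes bright enough to compare. All 23 were higher in Ex2, 19 of them at least 2-fold, with a median difference of 2.06 (interquartile range 1.22 to 3.01). None of the 10000 random lists had a higher median. With no brightness filter the median was 1.02. TBG4 was 8.81-fold and TBG3 8.67-fold higher, and the ripening expansin gene EXP1 differed by 1.55. PG2, the fruit polygalacturonase gene and the brightest of the list, differed by 0.29, a direction that turned with scaling on the spikes.

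Of 23 secreted defence and stress genes, 14 were bright enough, some through their Ex2 value alone, as was SBT1 (5.43 on Ex1). Their median was 2.55, with 12 at least 2-fold higher in Ex2 and 0 at least 2-fold lower. This median too lay above all 10000 random lists. The subtilase genes SBT1 and sbt3 were 8.00-fold and 7.45-fold higher, the glucanase gene GluB 7.17-fold and the chitinase gene CHI17 6.26-fold. The brightest member, the osmotin-like gene NP24-I, differed by 1.03, below the shift brought by scaling on the spikes. TPx1, which entered this list by its symbol and whose older name LeTPx1p is that of a thioredoxin peroxidase, was the exception, at -0.48. PR5 (now LOC543878), outside the list, was 9.01-fold higher.

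Of 11 membrane transporters, channels and pumps, 6 were bright enough, some through their Ex2 value alone, as was LHA1 (7.09 on Ex1). All 6 were at least 2-fold higher in Ex2, with a median of 2.42 at percentile 99.96 of random lists. They included the plasma membrane proton pump genes LHA1 (7.81-fold) and LHA2 (4.43-fold), the phosphate transporter gene PT1 (6.66-fold) and the hexose transporter gene HT3 (6.45-fold). Vacuolar and lysosomal-type hydrolases had 3 bright members with a median of 1.87 at percentile 95.7, inside the range of random lists. Among them lin5, a cell wall invertase gene, was 7.01-fold higher, CYP1 3.66-fold, and the acid invertase gene AI differed by 0.50.

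The ethylene signalling list had a median of 0.79 over 12 members, 6 of them at least 2-fold higher, at percentile 99.75. With scaling on the spikes its median was -0.40, and with the upper-quartile filter it lay inside the range of random lists. The members divided by protein type, a split made after the values were seen. EIN2, whose protein sits in the endoplasmic reticulum membrane, was 8.91-fold higher, and the receptor genes ETR1, ETR6 and ETR2 were 6.11-fold, 5.54-fold and 3.03-fold higher. ETR3 (now LOC544279) and ETR4, the brightest receptors, were 2.18-fold and 2.09-fold higher, less than the shift between spikes and deposited scale. The soluble CTR kinases and EIL transcription factors differed by 0.17 to 0.51.

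**Figure D1:**
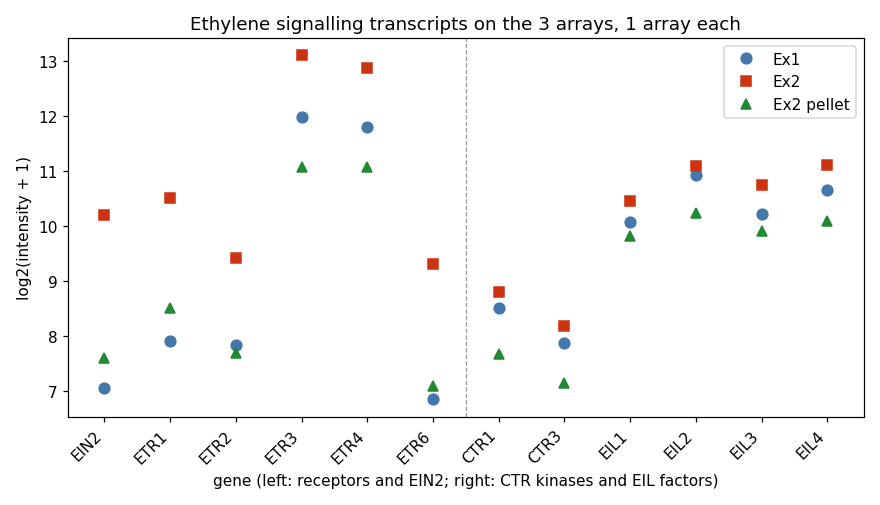
Log2(intensity + 1) of 12 ethylene signalling genes (x axis) on the 3 arrays, 1 symbol per array, with receptors and EIN2 left of the dashed line and CTR kinases and EIL factors right of it. Left of the line the Ex2 symbols lie 1.07 to 3.15 above the Ex1 symbols, and right of it 0.17 to 0.51 above.

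The other lists set beforehand with at least 3 bright members lay inside the range of random lists. Ethylene synthesis and ripening enzymes had a median of -0.03 over 13 members (percentile 89.3), with E8, the brightest, at -0.02 and ACS1A at -0.62. The lipoxygenase gene loxC, at 2.33-fold higher, was the 1 member past 2-fold. Glycolysis and carbon metabolism had a median of 0.16 over 6 members (percentile 83.7), with SPS at 0.56. Carotenoid and isoprenoid enzymes had a median of 0.23 over 10 members (percentile 96.5), led by DXS at 0.66. Transcription factors had a median of -0.48 over 13 members, all 13 below 0, at percentile 21.8, with ERF3 at -1.0 and the ripening regulator NOR at -0.93. Photosynthesis proteins had a median of -0.55 over 4 members (percentile 20.0), and PSBR was at -0.67. The signs of the glycolysis and carotenoid medians turned with scaling on the spikes, that of glycolysis also with no filter, and those of the ethylene synthesis and transcription factor medians with scaling on ribosomal proteins.

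The lowest named genes in Ex2 relative to Ex1 were LOC778319 at -1.44, the metallothionein gene MT2 at -1.43, adc1 at -1.42 and the phosphate starvation gene TPSI1 at -1.39. They were followed by the metallothionein gene MTA at -1.34, LOC544081 at -1.29, the mitochondrial import gene TIM10 at -1.26 and the transcription factor gene DREB3 at -1.19. LOC544187 was at -1.18, the copper chaperone gene CCH at -1.17, the mini zinc finger gene matriochka at -1.14 and psaD (now LOC543978) of photosystem I at -1.10. Each of these differences was larger in size than the 0.55 shift brought by scaling on ribosomal proteins.

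The second comparison, pellet minus Ex2, set the debris pellet against the Ex2 supernatant extract. Transcripts of cell wall enzymes, ethylene signalling proteins and membrane transporters were lower in the pellet, by up to 6.48-fold. The 16 small cytosolic proteins, a list made after the data were examined, were all higher there (percentile 100), with MTA at 4.12-fold. The list holds genes named as highest in this comparison, among them MTA, CCH, MT2 and sumo, so its percentile is no separate support. Of 499 named genes, 46 were at least 2-fold higher in the pellet and 107 lower. Of 5538 probe sets, 943 were higher and 1095 lower. The named genes split 19 to 160 with scaling on ribosomal proteins and 130 to 55 on the spikes, and the probe sets split 381 to 1548 and 1994 to 567.

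The lowest named gene in the pellet was TBG1 (6.48-fold lower), followed by TBG5 (6.21-fold), EIN2 (6.08-fold), the Verticillium resistance receptor gene Ve2 (5.80-fold) and TBG2 (5.78-fold). NHX2, a cation/proton antiporter gene, was 5.67-fold lower, LHA1 5.20-fold, the endoglucanase gene Cel3 5.11-fold and the receptor gene Eix1 4.90-fold. All 23 cell wall genes were lower in the pellet, 17 at least 2-fold, with a median of -1.36, below all 10000 random lists. With no brightness filter the cell wall median was -0.74. PG2 was at -0.13, a sign that turned with scaling on the spikes. All 6 transporters were at least 2-fold lower (median -2.05, percentile 0.04), and of the 12 ethylene signalling genes 9 were (median -1.43, percentile 0.01). ETR6 was 4.70-fold and ETR3 4.11-fold lower in the pellet than in Ex2.

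Secreted defence genes were nearer to their Ex2 level in the pellet, with a median of -0.67 over 14 members and 3 at least 2-fold lower. Their percentile of 2.29 lay just outside the range of random lists, and 4 of the alternatives brought it inside. SBT1 was 4.33-fold and sbt3 3.05-fold lower, GluB was 2.01-fold lower, and NP24-I was at -0.24, which turned with scaling on the spikes. The vacuolar and lysosomal-type list had a median of -1.34 over 3 members (percentile 6.08), with lin5 at -1.93 on the log2 scale.

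The named genes highest in the pellet were LOC778319 at 5.31-fold, TPSI1 at 4.44-fold, LOC544081 at 4.36-fold, MTA at 4.12-fold, CCH at 4.06-fold and MT2 at 3.77-fold. PsbQ of photosystem II was 3.63-fold higher, LOC543632 3.46-fold, LOC544298 3.28-fold, DDTFR19 3.09-fold and the small modifier gene sumo 3.07-fold. The 4 photosynthesis genes had a median of 1.03, inside the range of random lists (percentile 97.4), with psaD at 2.44-fold, CAB4 at 2.29-fold and PSBO at 0.11 on the log2 scale. Transcription factors had a median of 0.42 (percentile 74.1) with PTI4 at 2.15-fold and TDR6 at 2.05-fold, and the sign of this median turned with scaling on ribosomal proteins. Carotenoid enzymes had a median of -0.42 (percentile 4.74) and glycolysis -0.44 (percentile 18.1), and both signs turned with scaling on the spikes. DXS was 2.79-fold, SPS 2.57-fold and loxC 4.84-fold lower in the pellet than in Ex2. The ethylene synthesis list had a median of 0 at percentile 21.9.

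**Figure D2:**
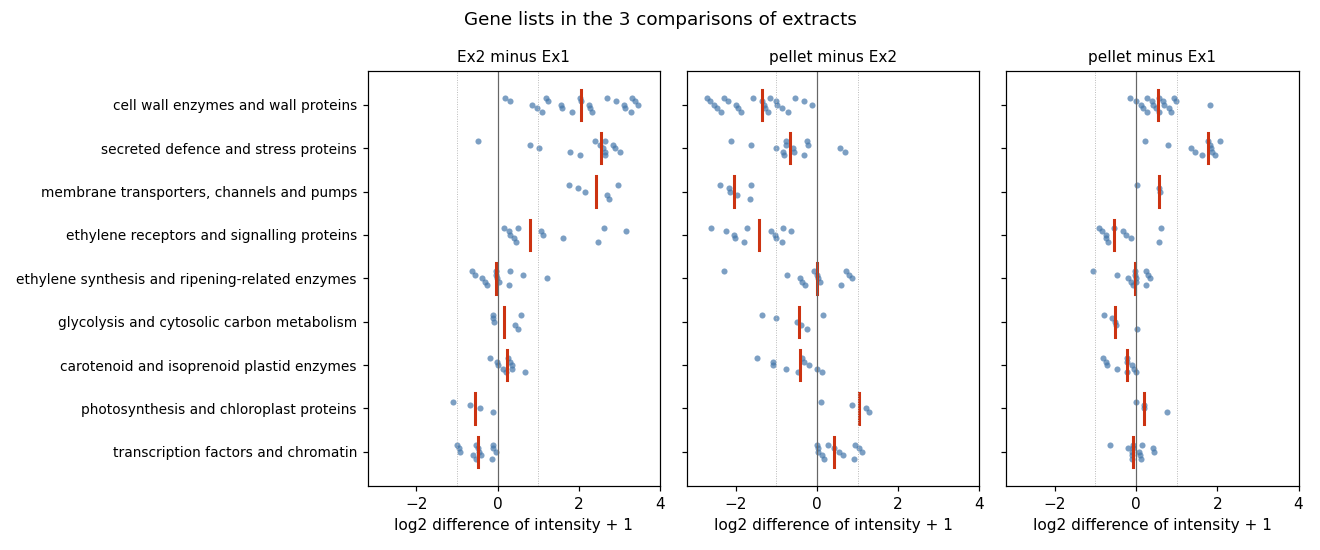
Log2 differences of intensity + 1 (x axis) for the members of 9 gene lists (y axis), with 1 point per gene and a red bar at the list median, in the 3 comparisons; dotted lines mark 2-fold. The cell wall median is 2.06 for Ex2 minus Ex1, -1.36 for pellet minus Ex2 and 0.53 for pellet minus Ex1, where the secreted defence median is 1.77.

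The third comparison, pellet minus Ex1, set the debris pellet against the direct phenol extract. Fewer genes were 2-fold apart here than in the other comparisons. Transcripts of secreted defence proteins such as chitinases and lipid transfer proteins were higher in the pellet, by up to 4.16-fold. The transcription factor genes DREB3 and WRKYIId and the cryptochrome gene CRY2 were the lowest named genes, while the transcription factor list lay inside the range of random lists. Of 471 named genes, 24 were at least 2-fold higher in the pellet and 12 lower. Of 5297 probe sets, 200 were higher and 253 lower. The named genes split 30 to 9 with centring on medians and with ribosomal scaling, and 8 to 87 with scaling on the spikes. The probe sets split 265 to 195 with ribosomal scaling and 36 to 1121 on the spikes.

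The secreted defence list had a median of 1.77 over 11 members (interquartile range 1.41 to 1.86), 9 of them at least 2-fold higher in the pellet and none below 0. It lay above all 10000 random lists. CHI17 was 4.16-fold higher, PR-P2 3.83-fold, PR1b1 3.67-fold, GluB 3.57-fold and the lipid transfer gene TSW12 3.51-fold. CHI3 and CHI9 were 3.40-fold and 3.10-fold higher, PR5 3.46-fold, LOC543883 2.98-fold and the acid phosphatase gene APS1 2.91-fold. Cell wall genes had a median of 0.53 over 18 members, above all random lists, with 1 of them, Cel1 at 3.52-fold, past 2-fold. The sign of the cell wall median turned with scaling on the spikes, as did that of the 3 transporters (median 0.57, inside the range of random lists). The median of the 2 bright genes on the vacuolar and lysosomal-type list (0.50) turned too. Of these, lin5 is a cell wall invertase gene.

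DREB3 was the lowest named gene in the pellet, 5.05-fold below Ex1, followed by the WRKY factor gene WRKYIId at 4.31-fold, the cryptochrome gene CRY2 at 3.05-fold, NML1 at 2.74-fold and the MAP kinase gene MAPK10 at 2.70-fold. LOC543600, also called TGA2.2, was 2.69-fold lower, the arginine decarboxylase gene ADC 2.62-fold, adc1 2.43-fold and AML1 2.31-fold. The aldehyde oxidase gene TAO2, loxC and CRY1A were 2.08-fold, 2.08-fold and 2.00-fold lower. Ethylene signalling genes had a median of -0.56 over 11 members (percentile 0.025), with ETR3 at -0.91 and CTR1 at -0.85, while ETR1 was at 0.60 and EIN2 at 0.55. By the split made after the values were seen, 5 receptor and EIN2 genes had a median of -0.13 (percentile 20.8) and 6 CTR and EIL genes one of -0.63 (percentile 0.19). The 10 carotenoid enzymes were all below 0 (median -0.23, percentile 1.91), with DXS at -0.82 and PDS at -0.74. The 5 glycolysis genes had a median of -0.51 (percentile 1.34), with SPS at -0.80. Of the alternatives, 4 brought the carotenoid list and 2 the glycolysis list inside the range of random lists. The ethylene synthesis list (median -0.02, percentile 22.5), the transcription factors (median -0.06, percentile 11.5) and photosynthesis (median 0.18, percentile 78.9) lay inside the range of random lists. Signs of those 3 medians turned with scaling, that of the transcription factors also without cross-hybridising designs.

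Several lists were too small for a percentile. In Ex2 minus Ex1, the ribosomal protein genes RPL8 and RPL3 were at -0.61 and -0.48, ER24 at -0.83, HSC80 at -0.01, the actin gene ACT at -0.55 and AOX1a at 0.10. The pair of epidermal lipid transfer genes, both also on the secreted defence list, had a median of 1.30 for Ex2 minus Ex1 and 1.41 for pellet minus Ex1. Of the green tissue markers, CAB4 alone was bright enough, at -0.43 for Ex2 minus Ex1 and 0.77 for pellet minus Ex1. No vascular marker, proteasome gene or endoplasmic reticulum chaperone of the lists set beforehand matched a named probe set, and the 1 seed marker was too dim. The 3' to 5' signal ratio of actin was 1.2 on Ex1, 1.71 on Ex2 and 1.35 on the pellet, and that of EF1a was 2.62, 3.27 and 2.81.

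The arrays were also ordered probe set by probe set. Of 2038 probe sets at least 2-fold apart between Ex2 and the pellet, Ex1 lay between the pair, ties included, in 1280, or 62.8% (Wilson 95% interval 60.7 to 64.9). In 640 it lay below both. Of 1524 probe sets 2-fold apart between Ex2 and Ex1, the pellet lay between in 63.8% (61.3 to 66.2). Of 453 probe sets 2-fold apart between the pellet and Ex1, Ex2 lay between in 41.3% (36.8 to 45.9) and above both in 243. These intervals cover counting only, and probe sets of 1 array are not independent.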

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

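The array carries 63 probe sets for reporter genes that are not tomato transcripts, and no comparison used them. Of these, 8 read above the highest of 59 probe sets for sequences treated here as absent, which read 23.7 on Ex1, 26.4 on Ex2 and 23.7 on the pellet, on all 3 arrays. Their lowest intensities on the 3 arrays were 71.5, 50.6, 48.7, 43.2, 38.6, 31.2, 29.8 and 27.7. The brightest had the same value of 71.5 on each array. All 8 were below the median intensity of each array.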

How the results depend on the processing

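Scaling on the spikes, random lists from named genes and the lists without TPx1 and ER24 were chosen after seeing the data. Of 317 alternative values of list medians, 282 kept both their direction and their side of the range of random lists. The sign was opposite in 17, 8 of them with scaling on the spikes and 5 with ribosomal scaling. Centring and the scalings on spikes and ribosomal proteins (29 values each) shift all genes alike, so they could not move a side. Random lists that were unmatched or from named genes (29 values each) leave the median as it is, so they could not turn a sign. Part of the 282 was therefore fixed in advance. Of 132 alternative counts, 88 stayed within 1.5 times the reported count. The medians of cell wall genes, secreted defence genes and transporters for Ex2 minus Ex1 kept direction and side under each alternative run. The cell wall median was 1.02 with no filter and 0.87 with scaling on the spikes. The comparison by signal sequence or membrane span and its alternatives were not run. No paired analysis was possible because each group holds 1 array. Single arrays and signal near background limit all values, and thresholds and filters change counts by construction; elsewhere the cause was not tested.

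Counts are given as higher/lower. For Ex2 minus Ex1, genes with scaling on the spikes were 50 and 320 and probe sets 438 and 3993. With ribosomal scaling the lower genes were 0 and the lower probe sets 28. With the upper-quartile filter there were 14 lower genes, and 606 higher and 297 lower probe sets. At 3-fold there were 0 lower genes and 21 lower probe sets, and at 1.5-fold 96 and 1725.

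For pellet minus Ex2, genes with scaling on the spikes were 130 and 55 and probe sets 1994 and 567. With ribosomal scaling the higher genes were 19 and the higher probe sets 381. With the upper-quartile filter there were 66 lower genes, and 592 higher and 635 lower probe sets. At 3-fold, genes were 13 and 52 and probe sets 255 and 538. At 1.5-fold there were 110 higher genes and 1712 higher probe sets.

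For pellet minus Ex1, genes with scaling on the spikes were 8 and 87 and probe sets 36 and 1121. With the upper-quartile filter, genes were 12 and 5 and probe sets 96 and 97. At 3-fold, genes were 9 and 3 and probe sets 43 and 58. At 1.5-fold, genes were 62 and 52 and probe sets 647 and 669.

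Of the medians of lists set beforehand that lay outside the range of random lists, those whose sign was turned by scaling on the spikes were the ethylene signalling list for Ex2 minus Ex1 (-0.40) and the cell wall list for pellet minus Ex1 (-0.12), with their places among random lists unmoved. Signs of medians inside the range turned too, as did those of glycolysis (-1.03) and carotenoid enzymes (-0.96) for Ex2 minus Ex1, the former also with no filter. For Ex2 minus Ex1, the ethylene signalling list came inside the range of random lists with the upper-quartile filter (1.07). Outside it came the vacuolar hydrolases with no filter (0.82), carotenoid enzymes with no filter (0.18) and the upper-quartile filter (0.24), and transcription factors against random lists from named genes (-0.48).

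For pellet minus Ex2, secreted defence genes came inside the range with the upper-quartile filter (-0.45), the mean of a gene's probe sets (-0.59), random lists from named genes (-0.67) and without TPx1 (-0.75). Outside it came vacuolar hydrolases with no filter (-0.44) and photosynthesis genes against named genes (1.03) and with quantile normalization (1.03). For pellet minus Ex1, glycolysis genes came inside with no filter (0) and with unmatched lists (-0.51). Carotenoid enzymes came inside with the mean of probe sets (-0.23), unmatched lists (-0.23), quantile normalization (-0.21) and without cross-hybridising designs (-0.22).

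The share of probe sets with Ex1 between Ex2 and the pellet was 56.6% at 3-fold, that with the pellet between Ex2 and Ex1 was 87.6%, and that with Ex2 between the pellet and Ex1 was 50.5%. The last was 34.6% with arrays centred on their medians.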

Other observations

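The lists in this part, and the tests of transcript length, array scaling, the secretory route alone, degradation and transcript size, were chosen after the data were examined. Membrane proteins outside the lists set beforehand were also higher in Ex2 than in Ex1. Of 16 further transporters and channels, 9 were bright enough, some through their Ex2 value alone, as was NHX2 (7.45 on Ex1). For pellet minus Ex1, 5 passed the filter. All 9 were at least 2-fold higher in Ex2, with a median of 2.11, which the filter favours. NHX2 was 6.26-fold, the aquaporin gene Aqp2 6.25-fold and the peptide transporter gene OPT1 5.23-fold higher. Of 6 receptor-like genes 2 were bright enough, Eix1 at 5.19-fold and Ve2 at 5.13-fold higher. Ve2 passed through its Ex2 value alone (6.50 on Ex1). Of 5 genes for proteins of the endoplasmic reticulum, the lowest difference was 0.28 and the median 1.6, with BI-1 at 4.30-fold and HMGR at 3.03-fold.

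Cytosolic families differed from one another. The 8 genes of 14-3-3 proteins were all lower in Ex2 than in Ex1 (median -0.42, percentile 35.4), a sign that turned with scaling on ribosomal proteins. The 7 MAP kinase cascade genes had a median of 0 for Ex2 minus Ex1 and -0.38 for pellet minus Ex1, with MAPK10 at -1.43. The 16 small cytosolic proteins, among them metallothioneins and ribosomal proteins, were all lower in Ex2 than in Ex1 (median -0.97, percentile 0). They had a median of 1.27 for pellet minus Ex2 (percentile 100) and 0.28 for pellet minus Ex1 (percentile 99.4). The 24 large cytosolic and nuclear proteins had medians of 0.29 (percentile 99.9), -1.0 (percentile 0) and -0.75 (percentile 0) in the same comparisons. The signs of the 0.29 and 0.28 medians turned with scaling on the spikes. Both lists hold genes named for these contrasts, so such percentiles are no separate support. MT2, MTA, TIM10 and CCH were named as lowest for Ex2 minus Ex1. Without them, 12 small cytosolic proteins had a median of -0.90. CRY2, ADC, TAO2 and CRY1A were named as lowest for pellet minus Ex1. Without them, 20 large cytosolic and nuclear proteins had a median of -0.62.

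The first pattern weighed is the excess of secretory-route transcripts in Ex2 over Ex1. Transcript length alone is argued against: 9 small secreted proteins exceeded 12 small cytosolic ones by 2.69 at the median. Genes named for this contrast were left out, which removed none of the secreted ones. All but 3 of the 9 were on the defence list, which is part of the pattern. Those 3 had a median of 0.90 and a lowest value of 0, and the highest of the 12 cytosolic ones was -0.33. The interquartile ranges of the 9 and of the 3 lay apart from the cytosolic one. A scaling factor per array as the whole cause is argued against too: it moves all genes alike, yet the lower quartile of the cell wall list lay 1.12 above the central 95% of random list medians. A candidate explanation is translation on the endoplasmic reticulum, a hypothesis from 1 array per group. Transporters were higher by 2.54 than traffic proteins made in the cytosol, such as Rab genes (medians 2.11 and -0.43, the latter turned by ribosomal scaling). Of 16 transporters 9 passed the filter, some through their Ex2 value alone, against 10 of 10 traffic genes. Part of this gap may therefore come from the filter, and no unfiltered value was computed for these lists. Of the 10 traffic genes 3 were above 0, with SAR2 at 0.94. The lists were not matched for size, and large cytosolic and nuclear proteins lay 1.25 above small cytosolic ones for Ex2 minus Ex1. RNA integrity also stays open, since 3' to 5' ratios were higher on Ex2 than on Ex1 for 4 of 4 control genes with both ends bright. Control genes with a dim end split: GlutTrans was lower on Ex2 (0.11 on Ex1, 0.08 on Ex2) and PhyB2 higher (33.3 and 40.5).

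The second pattern is that secreted defence genes were lower in Ex1 than in both Ex2 fractions. For the secretory route alone, the defence median for pellet minus Ex1 exceeded the higher of the cell wall and transporter medians by 1.2. That higher median rests on 3 bright transporters. The test rereads medians that had already shown the pattern, so it adds no separate support. It does show that lists sharing the route differed: the defence lower quartile was 1.41 and the cell wall upper quartile 0.78. For a broad defence response in the tissue used for the Ex2 fractions, defence genes of proteins that are not secreted showed no rise as a set. Their median was -0.40 with an upper quartile of -0.27, from 7 bright genes of 20. Tissue and extraction cannot be separated here: large cytosolic and nuclear proteins were low too (median -0.75), so a lowering by extraction could hide a rise. A broad response therefore stays open. A response confined to secreted defence proteins, a difference in the fruit used or another share of epidermis may remain too, all untested. The secretory route acting together with transcript size was not tested either. For pellet minus Ex1, large cytosolic and nuclear proteins had a median of -0.75 and small cytosolic ones 0.28. The pair of epidermal genes had a median of 1.41 there. Both are on the secreted defence list, so they give no separate reading on epidermis.

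The third pattern is the set of transcripts lower in the pellet than in Ex1. Without the genes already named as lowest, 20 large cytosolic and nuclear proteins had a median of -0.62. They lay 0.89 below the small cytosolic ones, which leaves room for a part played by transcript size, with protein size standing in for transcript length. The lowest named genes, DREB3 at -2.34 and WRKYIId at -2.11, were on neither size list, so the test does not cover them. For RNA degradation in the pellet, 4 of 4 internal control genes with both ends bright had a higher 3' to 5' ratio in the pellet than in Ex1, GAPDH by less than 0.01. All 4 ratios were higher still on Ex2, where the large proteins lay 1.25 above the small ones at the median, against degradation acting alike on each array. Ex2 is another fraction on 1 array, so degradation confined to the pellet stays open.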
